A study of Mus musculus with 2 samples.

How the data were processed

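H3K27me3, trimethylation of lysine 27 on histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain of mice at postnatal day 0. The mark is deposited by the Polycomb repressive complex PRC2 and lies over silent developmental genes. The labels gave 1 group of 2 biological replicates, each a pool of mice of both sexes. Replicate 1 came from 15 mice per the labels, and the number of mice behind replicate 2 is not given in the sources used here.

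The deposited files were 4 peak lists in mm10 coordinates. Per the notes deposited with each sample, the authors called peaks on each replicate (2 technical replicates together), called another list on both replicates pooled, and derived a list of replicated peaks from these. The notes named the same 2 further input files for both replicates. The peak caller, aligner and overlap rule behind the replicated list are not given in the sources used here. Each peak carried a fold enrichment, a linear ratio, as the authors deposited it. Each also carried a −log10 p and a −log10 q that the authors' caller gave and that were deposited with the peak. These are the peak's own values and were used only to rank, filter or describe peaks within a list. The smallest −log10 p was 2.01 in replicate 1, 2.02 in replicate 2 and 2.03 in the pooled list, so the lists included weak peaks. Of the peaks, 77.3% in replicate 1, 43.9% in replicate 2, 63.0% in the pooled list and 95.1% in the replicated list had a q of 0.05 or less.

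Read depth is unknown because the lists hold no read counts, so a gene without a peak was not detectably marked at an unknown depth, and list length cannot be set against depth. Every replicated peak was found, with the same coordinates and values, in the pooled list. Of the 18312 replicated peaks, 14836 (81.0%) overlapped peaks of both replicate lists, 3476 did not, and 670 pooled peaks that overlapped both were left out of the authors' list.

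Peaks were compared with the GENCODE mouse release M21 annotation and the mouse GRCm38 sequence, whose chromosome lengths are those of mm10. Chromosomes 1 to 19 and X were used, which left out 1 peak of replicate 1 on another scaffold. The 21755 protein-coding genes of these chromosomes each had 1 transcription start site (TSS), the 5′ end of the annotated gene. A promoter was the TSS ± 1 kb and was called marked when at least 1 bp of it lay in a replicated peak. Coverage around a gene was the number of bp in peaks within 10 kb on either side of its TSS, a window of 20001 bp. Domains were replicated peaks joined across gaps of up to 3 kb. Annotation shares counted each bp once, with promoters before exons, exons before introns, and the rest as intergenic.

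Replicate peaks were called shared when they overlapped by at least 1 bp, and chance was taken from 100 circular shifts of 1 list within each chromosome (one-sided). The fold enrichments of shared peaks were correlated across peaks, which are not independent replicates, so no p was computed. Promoter marking of 13 gene lists was tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The lists were Hox genes, regulators of midbrain, forebrain, hindbrain and spinal cord and non-neural lineages, morphogens, pan-neuronal genes, transmitter identity, glia and progenitors, blood, vessel and mesenchyme, pluripotency and germline, imprinted genes and housekeeping genes. No gene stood in more than 1 list and each listed gene was found in the annotation. Midbrain regulators were compared with 4 other lists in the same way, and 30 gene families defined by symbol prefix were tested as a separate set. Prefixes also take genes outside the family proper, such as Fgfr3 among the Fgf genes. These tests count genes within 1 peak list, so their p-values do not measure variation between mice. Neighbouring genes share peaks and are not independent. The p-values of lists and families with clustered genes, such as Hox, may therefore be too small. Counts in each replicate's own list are given beside the lists, and for families where they change the call or the count by over 1.5 times. Intervals are exact (Clopper-Pearson, 95%) and cover counting error only.

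Lists, family prefixes, the tests of the lists, of the regional comparisons and of replicate sharing, and the rule for naming genes were fixed before the data were examined. The families were given the same Fisher test as the lists, which had not been written down for them in advance. The rule took the 10 genes with most covered bp around the TSS, up to 4 marked members of each list with most covered bp, up to 3 unmarked members in alphabetical order, the genes in the 10 widest domains, up to 5 promoters per direction marked in 1 replicate alone with most covered bp, and 15 genes chosen in advance. Alternatives fixed with them were an overlap of 50% of the shorter peak, the more significant 50% of each list, equal list lengths, promoter windows of ± 2.5 kb and ± 500 bp, 500 bp of the window covered, the pooled list, each replicate's list alone, strata by promoter CpG content (exact Cochran-Mantel-Haenszel test over 10 strata) and a denominator without unknown bases. Added after seeing the data were family tests on each replicate's list, autosomes alone, any annotated transcript start, and mean covered bp around the TSS compared by 100000 permutations of list membership. So were the tests of overall depth and of even X copies, of the X promoters against the rest of X, and of the ribosomal DNA peaks.

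The overlap code returned the bp found by direct counting in 100.0% of 500 simulated windows. It found 51.05% of 2000 simulated peaks shared where 50% had been placed on the other list and the rest at random. Simulated lists of 25 genes, each gene drawn independently, were tested against the 21755 genes at an unadjusted p under 0.05. The Fisher test called 1.8% of 500 lists drawn at the background share of 9.74%. It called 37.6% of those with a true share of 20%, 79.8% of those at 30% and 100.0% of those at 50%. With 48 genes it called 4.2%, 66.2%, 96.8% and 100.0% at these shares. In a list of 25 genes, a true share near 20% would therefore often be missed. Neither the adjustment over lists nor peaks shared by neighbouring genes were simulated. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3.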

Results

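H3K27me3 was mapped in midbrain from newborn mice (postnatal day 0) in 2 biological replicates, each a pool of mice of both sexes. Replicate 1 had 65397 peaks over 25.1 Mb, or 0.952% of chromosomes 1 to 19 and X, with a median width of 273 bp. Replicate 2 had 53199 peaks over 17.02 Mb, or 0.646%, with a median width of 247 bp. The authors' pooled list held 58999 peaks over 24.8 Mb, and 18312 of these, covering 13.7 Mb with a median width of 514 bp, made up the replicated list. Median fold enrichment, as the authors' caller gave it, was 3.23 in replicate 1, 3.06 in replicate 2 and 3.51 in the replicated list. Read depth is unknown. With 1 tissue at 1 age, the design allows comparison of the replicates with each other and of gene groups within the tissue.

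The widest H3K27me3 domains lay over the 4 Hox clusters, whose genes encode the homeodomain factors that pattern the trunk and hindbrain. The HoxC domain (chromosome 15, 102900071 to 103090011, mm10) was 189.9 kb wide and 87.8% of it lay in peaks. The HoxA domain (chromosome 6, 52143539 to 52328448) spanned 184.9 kb from Hoxa1 to Evx1 and was 80.6% covered. The HoxB domain (chromosome 11, 96233276 to 96377318) spanned 144.0 kb from Hoxb9 to Hoxb1, and the HoxD domain with Evx2 (chromosome 2, 74639958 to 74770741) spanned 130.8 kb. Hoxb13, at the far end of the HoxB cluster, lay with Ttll6 in a separate domain of 70.2 kb (chromosome 11, 96153007 to 96223178). The other 5 of the 10 widest domains held Scn5a, the cardiac sodium channel gene (chromosome 9, 119512521 to 119589554, 77.0 kb), Camkmt (chromosome 17, 85436720 to 85494180, 57.5 kb), the heart and limb factor Tbx5 (chromosome 5, 119791263 to 119847556, 56.3 kb), no protein-coding gene (chromosome 5, 101499889 to 101554397, 54.5 kb) and the neural crest factor Tfap2a (chromosome 13, 40698073 to 40750279, 52.2 kb). The Camkmt domain lay 119427 bp from Six3, and the domain without a gene lay 103741 bp from Nkx6-1, the nearest protein-coding gene. In all, joining peaks across gaps of up to 3 kb gave 7699 domains with a median width of 577 bp, of which 420 were wider than 10 kb and 61 wider than 30 kb.

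**Figure D1:**
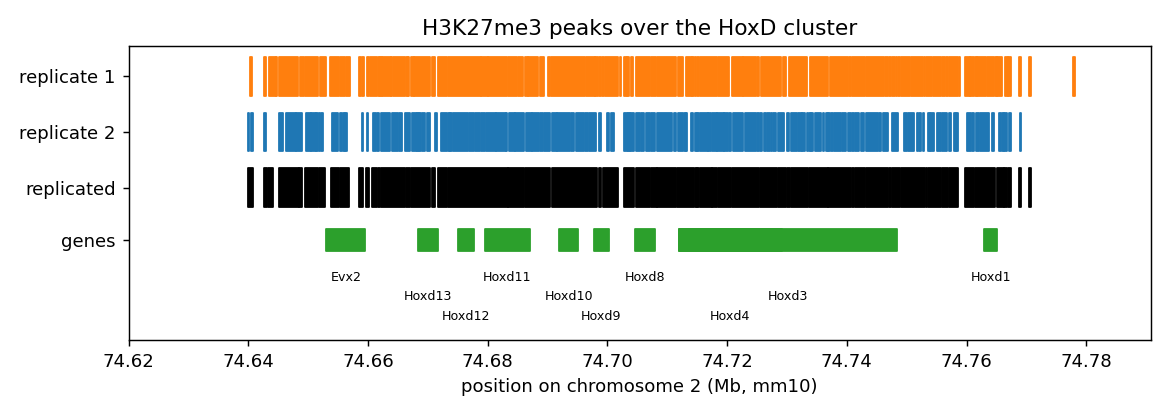
Peaks of replicate 1, replicate 2 and the replicated list over the HoxD cluster, by position on chromosome 2 (Mb, mm10), with Hox and Evx2 gene bodies as green bars. The replicated peaks covered 85.4% of the 130.8 kb domain, and both replicates had peaks along it.

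Of the 10 genes with most covered sequence around the TSS, 8 were Hox genes. Hoxb3 (chromosome 11, 96323326 to 96347930) and Hoxb4 (chromosome 11, 96318267 to 96321638) had 19560 of 20001 bp in replicated peaks each, Hoxa6 (chromosome 6, 52206288 to 52208722) 19480 bp, and Hoxc6 (chromosome 15, 102998257 to 103011881) 19395 bp. Hoxb4 had 19358 bp in peaks of replicate 1 and 15707 bp in those of replicate 2, and Hoxa6 had 19032 and 16664 bp. Hoxa3 had 19337 bp, Hoxa4 19336 bp, Hoxb5 19311 bp and Hoxc4 19307 bp. Gm28308, an annotated gene model that overlaps Hoxa3, had 19337 bp. Cdx2, the intestinal and trophoblast homeobox gene (chromosome 5, 147300805 to 147307270), had 19425 bp, with 19066 bp in replicate 1 and 15700 bp in replicate 2. These windows overlap within a cluster, so neighbouring Hox genes are not independent.

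Promoters of developmental regulators carried the mark across regional and lineage lists. Among all 21755 protein-coding genes, 2120 promoters (9.74%) were marked by replicated peaks. All 39 Hox promoters were marked (100%, 95% CI 91.0 to 100), as were all 26 promoters of hindbrain and spinal regulators (CI 86.8 to 100). Forebrain regulators followed with 27 of 30 (90.0%, CI 73.5 to 97.9), non-neural regulators with 41 of 48 (85.4%, CI 72.2 to 93.9), midbrain regulators with 25 of 30 (83.3%, CI 65.3 to 94.4) and morphogens with 39 of 48 (81.3%, CI 67.4 to 91.1). Each of these 6 shares lay above that of the other protein-coding genes (Fisher's exact test, adjusted p = 3.45e-39 for Hox, 1.44e-26 for hindbrain and spinal, 3.37e-24 for forebrain, 5.87e-34 for non-neural, 8.75e-21 for midbrain and 7.99e-31 for morphogens). The replicates' own lists marked 39 and 39 Hox, 26 and 26 hindbrain and spinal, 28 and 25 forebrain, 41 and 41 non-neural, 29 and 25 midbrain, and 41 and 39 morphogen promoters, in replicates 1 and 2 respectively.

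**Figure D2:**
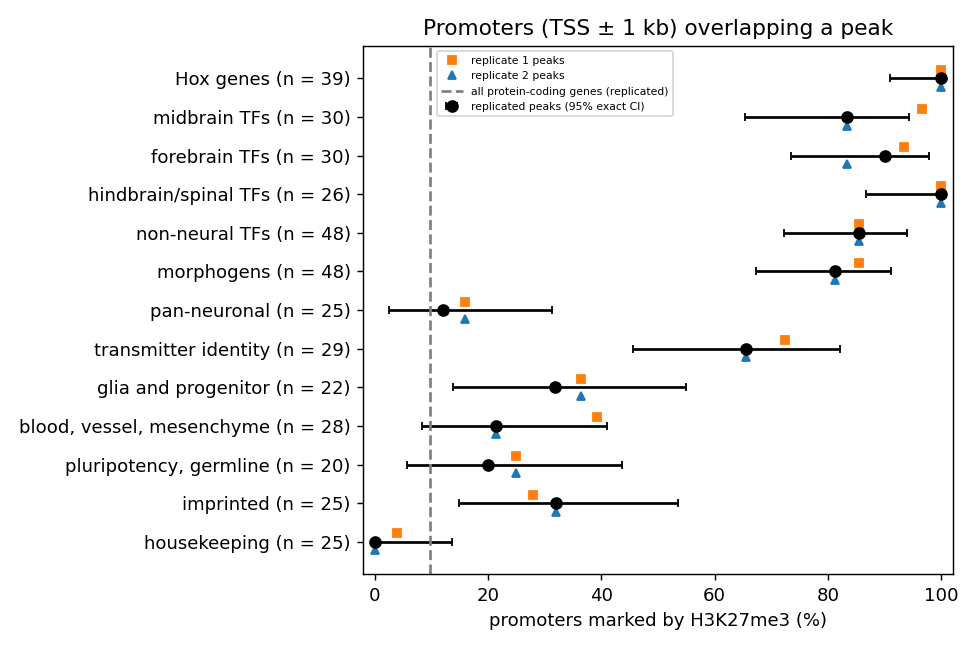
Share of promoters (TSS ± 1 kb, %) overlapping an H3K27me3 peak in each of the 13 gene lists, with n genes per list. Black points are replicated peaks with exact 95% CIs, orange squares and blue triangles are replicates 1 and 2 alone, and the dashed line is the 9.74% of all protein-coding genes; Hox genes stood at 100% and housekeeping genes at 0%.

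Forebrain regulators with most coverage were Gsx2 (chromosome 5, 75075601 to 75077893), which patterns the ventral telencephalon, with 18731 bp, Fezf2 (chromosome 14, 12342094 to 12348189) with 16988 bp, Six3 (chromosome 17, 85613608 to 85629302) with 16839 bp and Dlx6 (chromosome 6, 6863334 to 6868568) with 16739 bp. Foxg1, the telencephalic forkhead factor, had 14219 bp and a promoter fold of 6.18. Bcl11b, Hesx1 and Neurod6 were the 3 unmarked members, with 1104, 0 and 238 bp. In the hindbrain and spinal list Tlx1 (chromosome 19, 45150680 to 45156943) had 18219 bp, Gbx2, which sets the hindbrain side of the midbrain-hindbrain boundary, 16061 bp, the motor neuron factor Mnx1 15934 bp and Evx2 15645 bp. Among non-neural regulators, Cdx2 was followed by Pax9 (17457 bp), the heart factor Nkx2-5 (17153 bp) and the kidney and gonad factor Wt1 (16525 bp). Hnf1a, Hnf4a and Myf5 were among its 7 unmarked members, with 309, 0 and 0 bp. Morphogens were led by Wnt1 (13443 bp), Fgf8 (12626 bp), Wnt10a (12297 bp) and Wnt3a (12119 bp), while Bmp5, Chrd and Fgf10 were among the 9 unmarked. Pax6 (17892 bp) and the proneural gene Neurog2 (13217 bp) were marked, Neurod1 was marked by 3 bp of a replicated peak, and Ascl1, another proneural gene, was unmarked with 877 bp.

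Regulators listed for the midbrain itself were also marked, with coverage that varied widely between genes. The peaks come from whole tissue and no expression was measured here. Whether cells that use these genes carry the mark is therefore unknown. Pax2 (chromosome 19, 44756045 to 44837871) had 17503 bp and a promoter fold of 7.01, Foxa2 (chromosome 2, 148042877 to 148046969) 16857 bp, Foxa1 15786 bp and Pax5 15179 bp. The engrailed genes En1 (chromosome 1, 120602418 to 120607992) and En2 (chromosome 5, 28165694 to 28172166) had 10974 and 7237 bp, and the dopaminergic factors Nr4a2 and Pitx3 had 6980 and 4996 bp. Otx2 (chromosome 14, 48657677 to 48673819), required for forebrain and midbrain identity, had 1377 bp and a promoter fold of 2.65, with 2079 bp in replicate 1 and 1709 bp in replicate 2. Lhx1, Meis2 and Tal2 were among the 5 unmarked midbrain regulators, although all 3 were marked in replicate 1 alone. The other 2, Tcf7l2 and Zfpm1, fell outside the naming rule and were chosen after their values were seen.

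The share of midbrain regulators marked did not pass the test against any of the 4 comparison lists, and 1 had an unadjusted p under 0.05. Midbrain minus the other list was -6.67 percentage points for forebrain (Fisher's exact test, adjusted p = 0.942), -16.7 for hindbrain and spinal (adjusted p = 0.109), -16.7 for Hox (p = 0.0127, adjusted p = 0.0507) and -2.08 for non-neural regulators (adjusted p = 1). Mean coverage around midbrain TSSs was 9369 ± 4996 bp (SD over 30 genes), against 18171 ± 1320 bp for the 39 Hox genes (permutation test, two-sided, adjusted p = 8e-05 from the smallest p the permutations can give), 11991 ± 3526 bp for 26 hindbrain and spinal genes (p = 0.0279, adjusted p = 0.0558), 11294 ± 5236 bp for 30 forebrain genes (adjusted p = 0.204) and 9205 ± 5828 bp for 48 non-neural genes (adjusted p = 0.905). The coverage comparison was chosen after the promoter result was seen, and with any annotated transcript start 29 of 30 midbrain promoters were marked, a difference of -3.33 points from both the Hox and the hindbrain and spinal lists, as on replicate 1's list alone. With at least 500 bp of the window covered, the difference was -26.2 points from the hindbrain and spinal list and -30.0 from Hox, and both passed Fisher's exact test (adjusted p = 0.0281 and 0.00101, within ranges of 0.0281 to 1 and 8e-05 to 0.870 over the alternatives).

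Genes of neurotransmitter identity were marked more often than other protein-coding genes, and no such difference was detected for genes shared by all neurons. Of 29 transmitter genes 19 were marked (65.5%, CI 45.7 to 82.1, adjusted p = 8.09e-13, Fisher's exact test; 21 and 19 in replicates 1 and 2). The most covered were Slc6a5, the glycine transporter of inhibitory neurons (11598 bp), the overlapping cholinergic genes Slc18a3 and Chat (10467 and 10410 bp) and the vesicular glutamate transporter Slc17a7 (6280 bp). Th, encoding tyrosine hydroxylase of dopamine neurons (chromosome 7, 142892752 to 142931128), had no replicated peak within 10 kb of its annotated 5′ end. That end lies 31114 bp from the start of a shorter Th transcript (142900014), around which replicated peaks also covered 0 bp, with 637 bp in replicate 1 and 441 bp in replicate 2. Dbh and Ddc were unmarked with 0 bp, and Gad1 was unmarked at its 5′ end but marked at another annotated start. Of 25 pan-neuronal genes 3 were marked (12%, CI 2.55 to 31.2, Fisher's exact test, adjusted p = 0.730; 4 in each replicate). These were the neurofilament genes Nefl and Ina and the surface glycoprotein gene Thy1, with 147, 314 and 122 bp of the promoter in peaks, and Celf4, Dcx and Elavl3 were unmarked. The 2 lists were not tested against each other.

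Glial and progenitor genes were marked at 7 of 22 promoters (31.8%, CI 13.9 to 54.9, Fisher's exact test, adjusted p = 0.00546; 8 in each replicate). They included Olig2 (chromosome 16, 91225457 to 91228677, 15650 bp) and Olig1 (10128 bp), the basic helix-loop-helix factors of oligodendrocytes, the precursor receptor gene Pdgfra (9411 bp) and Sox10 (4133 bp), while Aldh1l1, Aqp4 and Cnp had no replicated peak within 10 kb. Blood, vessel and mesenchyme genes, which mark other cell types that midbrain tissue holds, were marked at 6 of 28 promoters (21.4%, CI 8.30 to 41.0, Fisher's exact test, adjusted p = 0.0642). Foxc1 (13116 bp), Pdgfrb (5079 bp), Col1a1 (4882 bp) and the endothelial gene Cldn5 (4076 bp) had most coverage, and Acta2, Aif1 and Alas2 were unmarked. By the same exact test this list had 11 marked promoters in replicate 1 (adjusted p = 0.00187) and 6 in replicate 2 (adjusted p = 0.183), the lowest and highest adjusted p over the alternatives.

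Imprinted genes were marked at 8 of 25 promoters (32.0%, CI 14.9 to 53.5, Fisher's exact test, adjusted p = 0.00309; 7 and 8 in replicates 1 and 2). Dlk1 (chromosome 12, 109452823 to 109463336) had 12262 bp, Grb10 (chromosome 11, 11930508 to 12038683) 10929 bp, Igf2 (chromosome 7, 142650766 to 142666816) 9929 bp and Kcnq1 4614 bp, and Cdkn1c, Igf2r and Impact were unmarked. On replicate 1's list the difference no longer passed the exact test (adjusted p = 0.103, against 0.000864 to 0.0159 over the other alternatives). Of 20 pluripotency and germline genes 4 were marked (20.0%, CI 5.73 to 43.7, Fisher's exact test, adjusted p = 0.146; 5 in each replicate), namely Prdm1, Pou5f1, Prdm14 and Lin28a with 4384, 3560, 3392 and 1774 bp around the TSS, while Dazl, Ddx4 and Dppa3 were unmarked. Housekeeping genes, with 0 of 25 promoters marked, did not pass the exact test either (adjusted p = 0.181). A count of 0, the lowest possible, gave an unadjusted p of 0.167 by Fisher's exact test. With 25 genes, this test on the replicated list could therefore not have detected depletion. The exact 95% CI was 0 to 13.7, and the approximate upper limit for a count of 0, 3 in 25, was 12%. Replicates 1 and 2 marked 1 and 0, and Actb, Atp5b and B2m were the members named by rule. The cell cycle inhibitor genes Cdkn2a (chromosome 4, 89274471 to 89294653) and Cdkn2b (chromosome 4, 89306299 to 89311039) were marked, with 16479 and 11556 bp.

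Replicated peaks were concentrated at promoters, which held 14.9% of their bp and 1.56% of the genome, a 9.61-fold excess. Exons held 9.56% against 3.27%, introns 31.8% against 35.2% and intergenic sequence 43.7% against 59.95%. Promoter shares were 9.47% in replicate 1 and 9.86% in replicate 2 (mean 9.67% ± 0.277, SD, n = 2). By promoter CpG content, 0.643% of promoters were marked in the lowest decile, 18.3% in the fifth and 7.72% in the highest.

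Promoters were marked in both replicates at 2134 genes, which was 67.6% of the 3155 marked in replicate 1 and 76.1% of the 2806 marked in replicate 2. Among promoters marked in replicate 1 and in neither replicate 2 nor the replicated list, most coverage by replicate 1 was at Zic1 (chromosome 9, 91358058 to 91365810, 11712 bp against 4392 bp in replicate 2), Slc16a2 (10923 against 1177 bp), Onecut2 (9907 against 6861 bp), Tsx (9588 against 1215 bp) and Lhx1 (9284 against 5220 bp). Slc16a2 (103697414 to 103821983) and Tsx (103414467 to 103424580) lie on X. In the other direction, Mzb1, Phpt1, Unc13a, Insm1 and Aqp2 had 3919, 3679, 3651, 3642 and 3632 bp in replicate 2, against 3972, 3540, 3572, 2324 and 5609 bp in replicate 1. At Phpt1 and Unc13a the promoter held 2 bp of a replicate 2 peak. Each is a single pair of libraries, with no test between them.

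Of the peaks, 26.6% in replicate 1 (17363) and 37.3% in replicate 2 (19853) overlapped a peak of the other replicate. Circular shifts gave at most 1.68% and 2.13%, and the Jaccard index of 0.194 compared with at most 0.00627 (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). The shares in replicates 1 and 2 were 31.0% and 36.9% on autosomes, and 6.14% and 55.2% on X. On autosomes sharing was highest among the most significant peaks, at 86.5% and 87.0% in the first decile of −log10 p in replicates 1 and 2, and 14.0% and 20.5% in the last. Fold enrichments of shared peaks correlated across peaks with a Spearman rho of 0.406 (95% bootstrap interval 0.374 to 0.432) and a Pearson r of 0.484. Peaks are not independent replicates.

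**Figure D3:**
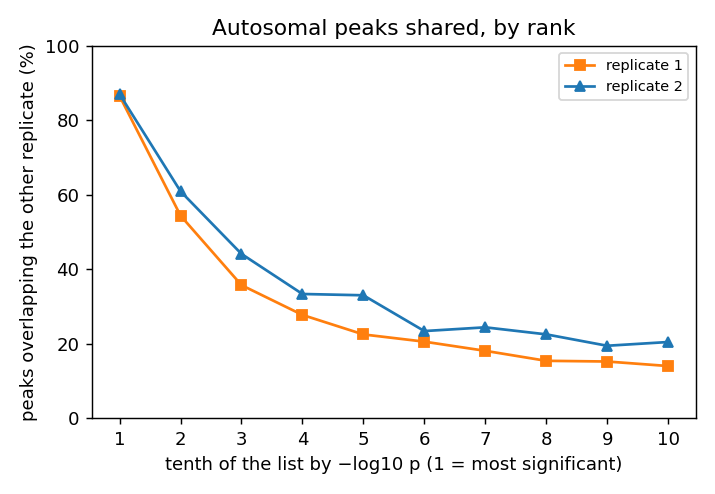
Share of autosomal peaks (%) that overlap a peak of the other replicate by at least 1 bp, by decile of −log10 p within each list, 1 being the most significant. Replicate 1 (orange squares) fell from 86.5% to 14.0% and replicate 2 (blue triangles) from 87.0% to 20.5%.

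The X chromosome differed most between the replicates. Replicate 1 had 11776 peaks on X and replicate 2 had 1268, a ratio of 9.29, while the 19 autosomal ratios lay between 0.928 and 1.09. Peaks covered 23.3 kb per Mb of X in replicate 1, above the range of 5.06 to 15.9 on its autosomes, and 1.91 kb per Mb in replicate 2, below its range of 4.24 to 11.9. X coverage relative to all autosomes was 2.73 in replicate 1, 0.282 in replicate 2 (mean 1.505 ± 1.73, SD, n = 2) and 0.694 in the replicated list. On X, 219 promoters were marked in replicate 1, 64 in replicate 2 and 67 of 948 in the replicated list. Of the 1294 replicated X peaks, 50.7% overlapped peaks of both replicates, against 83.3% on autosomes. With 1 value of X per list and 2 lists, no test was possible.

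**Figure D4:**
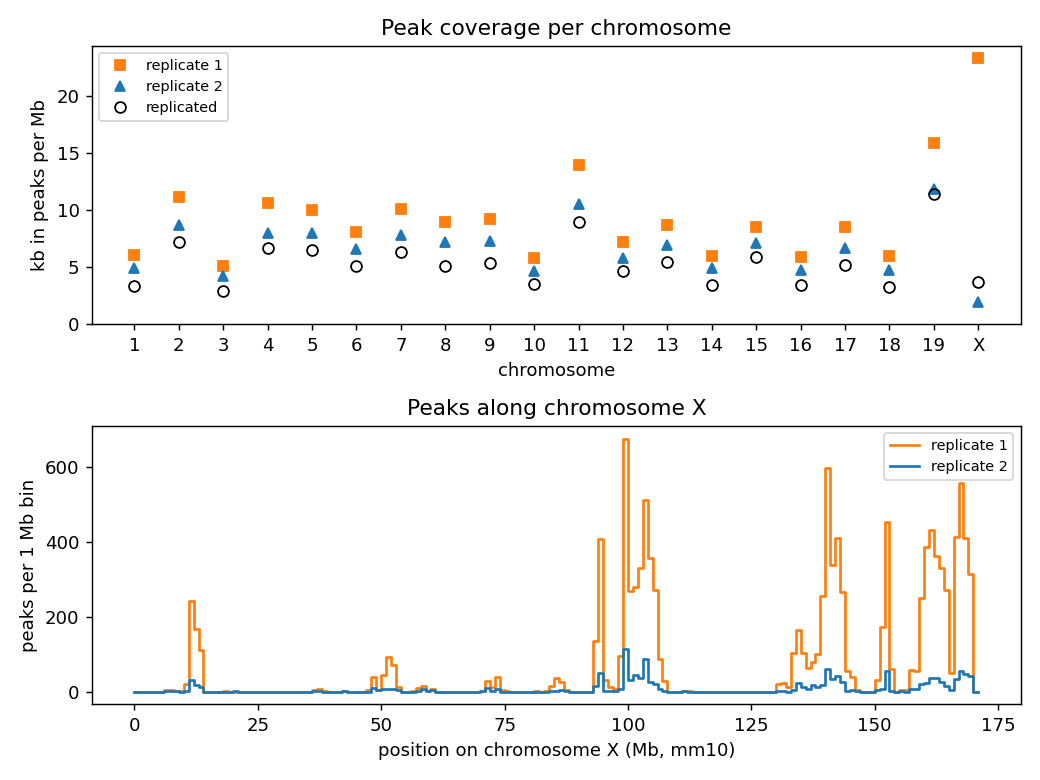
Upper panel, kb in H3K27me3 peaks per Mb of each chromosome in replicate 1 (orange squares), replicate 2 (blue triangles) and the replicated list (open circles), with X at 23.3, 1.91 and 3.69. Lower panel, peaks per 1 Mb bin along X (Mb, mm10), where replicate 1 had 11776 peaks and replicate 2 had 1268.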

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

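Family tests, autosomes alone, any annotated transcript start and mean coverage around the TSS were chosen after seeing the data, and the other alternatives were fixed before. Under the alternatives fixed in advance 142 values kept their direction and their side of the threshold, or moved by less than their spread, as did 84 under the added ones. Of the rest, 9 and 2 moved, 10 and 6 changed sign, 10 and 9 gained the call and 1 and 2 lost it, respectively. Some of the 142 could not change, such as the Jaccard index with a 50% overlap. The number of lists passing above other genes, 9 or 10, counted as kept. X coverage counted as kept from 0.282 to 1.41, its spread being an SD of 1.73 over 2 values. The 9 lists that passed included 8 that passed under every alternative run, and for the changes below the cause was not tested. No paired analysis was possible because there is 1 group. Differences are percentage points from other protein-coding genes unless stated. Pan-neuronal genes, never past the threshold, changed sign to -0.692 (TSS ± 2.5 kb), -4.03 (± 500 bp), -6.89 (500 bp covered), -3.05 (more significant 50% of peaks), -2.72 (pooled list) and -0.911 (CpG strata). Blood, vessel and mesenchyme genes passed with ± 500 bp (13.4), 500 bp covered (14.6), the pooled list (17.4), CpG strata (14.2), any start (13.4) and autosomes alone (13.2), and ranged from 8.54 to 24.8 with 1 replicate left out, passing on replicate 1's list only. Imprinted genes ranged from 13.5 to 19.1 with 1 replicate left out and lost the call on replicate 1's list. Housekeeping genes passed with the pooled list (-14.7). Midbrain against forebrain regulators, -6.67 as reported, stood at -10.0 with ± 500 bp, -13.3 with 500 bp covered, -13.3 with the more significant 50% of peaks and 6.67 with any start, and ranged from 0 to 3.33 with 1 replicate left out, none past the threshold. Against hindbrain and spinal regulators the gap of -16.7 passed with 500 bp covered (-26.2), stood at -20.0 with CpG strata and -3.33 with any start, and ranged from -16.7 to -3.33 with 1 replicate left out. Against Hox, with the same range and the same value for any start, it passed with ± 500 bp (-26.7), 500 bp covered (-30.0), the more significant 50% of peaks (-30.0) and mean coverage (-8802 bp). Against non-neural regulators, -2.08 as reported, it was -21.6 with CpG strata, -13.3 with the more significant 50% of peaks, 1.25 with ± 2.5 kb, 1.25 with the pooled list, 11.3 with any start, -2.08 to 11.3 with 1 replicate left out and 164 bp in mean coverage, none past the threshold. In the regional comparisons, CpG strata with genes of only 1 list, or with all genes marked or all unmarked, were left out. The gaps of -20.0 and -21.6 therefore cover fewer genes than those of -16.7 and -2.08. They cannot be read as a widening once CpG content is matched. The number of the 4 regional comparisons that passed rose from 0 to 1 (± 500 bp), 2 (500 bp covered), 1 (more significant 50% of peaks) and 1 (mean coverage). The promoter share of peak bp, 14.9%, was 16.7% in the more significant 50% of peaks, 10.8% in the pooled list, 15.4% on autosomes and 9.47% to 9.86% with 1 replicate left out. X over autosome coverage, 0.694, ranged from 0.282 to 2.73 with 1 replicate left out. With 1 replicate left out, Gabr genes ranged from -7.64 to 11.8 and Psm genes, 0.256 as reported, from -6.91 to -4.51, none past the threshold. The correlation of shared peaks was 0.439 with −log10 p. Unknown read depth limits all of these, since weak peaks may depend on it.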

Other observations

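Tests of gene families, of overall depth and of even X copies for the X difference, of the X promoters against the rest of X and of the ribosomal DNA peaks, and the comparison of mean coverage between regional lists were chosen only after the results were seen. Gene families, whose symbol prefixes but not their test were fixed in advance, extended the contrast between developmental regulators and other genes (Fisher's exact test, adjusted over 30 families). By this exact test, above the 9.74% of all promoters lay Wnt ligands with 19 of 19 marked (adjusted p = 5.69e-19), Nkx with 13 of 14 (4.40e-12), Lhx with 7 of 8 (1.65e-06), Pax with 9 of 12 (4.35e-07), Tbx with 9 of 15 (5.65e-06), Fox with 27 of 46 (2.10e-15), Sox with 11 of 19 (7.93e-07), Bmp with 7 of 16 (0.000916) and genes with the Fgf prefix with 10 of 31 (0.000983). Also past the exact test were 5 of 6 sine oculis homeobox genes (Six1, Six2, Six3, Six5 and Six6, adjusted p = 0.000111) and 5 of 9 with the Gata prefix (Gata2 to Gata6, adjusted p = 0.00148). Each of these families and the Hox genes also passed on each replicate's list. Members named here were chosen after their values were seen. Potassium channel genes (Kcn) were marked at 29 of 94 promoters (Fisher's exact test, adjusted p = 3.96e-08; 42 and 36 in replicates 1 and 2) and solute carriers (Slc) at 52 of 385 (adjusted p = 0.0250; 79 and 75).

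Genes with the prefixes Olfr, Vmn, Zfp, Pcdh, Hist, Nduf and Defb lay below other genes. Families, unlike the lists, were not tested within CpG strata. Of all promoters in the 2 lowest CpG deciles only 0.643% and 2.02% were marked. How far promoter CpG content accounts for the low shares was therefore not tested. By Fisher's exact test, olfactory receptors (Olfr) were marked at 1 of 1135 promoters (Olfr63, adjusted p = 5.97e-49; 11 and 12 in replicates 1 and 2), vomeronasal receptors (Vmn) at 0 of 331 (adjusted p = 1.52e-14; 1 and 1), genes with the Zfp prefix at 8 of 397 (adjusted p = 4.62e-09; 18 and 13), protocadherins at 1 of 69 (Pcdh8, adjusted p = 0.0232; 3 and 2), histone genes at 1 of 67 (Hist1h1b, adjusted p = 0.0310; 2 and 1), mitochondrial Nduf genes at 0 of 46 (adjusted p = 0.0310; 1 and 2) and beta-defensins (Defb) at 0 of 42 (adjusted p = 0.0449; 2 and 1). By the same exact test these also passed on each replicate's list, except Nduf on replicate 2's (adjusted p = 0.142, against 0.0163 on replicate 1's) and Defb on replicate 1's (0.0988, against 0.0462 on replicate 2's). On the replicated list Fisher's exact test did not separate Irx (Irx4 and Irx6, 2 of 6, adjusted p = 0.131), Pou (Pou4f1, Pou4f2, Pou4f3 and Pou5f1, 4 of 16, 0.0790), Gabr (Gabrd, 1 of 19, 1), Gri (Grid2ip, Grik3, Grin2c and Grin3b, 4 of 24, 0.318), Krt (Krt7, Krt8, Krt18, Krt71 and Krt87, 5 of 113, 0.0727), Cyp (8 of 107, 0.552), Rpl (Rpl3l, 1 of 57, 0.0557), Rps (Rps6ka4, 1 of 45, 0.144) or Psm (Psmb8, Psmb9, Psmd5, Psmd10 and Psmf1, 5 of 50, 0.842) from other genes. Irx passed on the lists of replicate 1 (5 of 6, exact test, adjusted p = 0.000675) and replicate 2 (3 of 6, 0.0413), as did Rpl below other genes (2 and 1 of 57, 0.0190 and 0.0132). Pou passed above other genes on replicate 2's list (6 of 16, exact test, adjusted p = 0.0165; replicate 1, 5 of 16, 0.0914), and Rps below them on replicate 2's (1 of 45, 0.0343; replicate 1, 4 of 45, 0.423). Gabr had 5 and 1 marked, Krt 11 and 13 and Psm 5 and 3 in replicates 1 and 2, and none of these 3 passed the exact test on either list.

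Replicate 1 covered 12.2 times as many bp of X as replicate 2, while the 19 autosomal ratios lay between 1.19 and 1.34, which argues against lower depth of replicate 2 as the whole cause. Peaks clustered, with 61.8% of replicate 1's X peaks in the busiest 17 of 168 bins of 1 Mb against at most 13.0% under even placement, but replicate 2's clustered as much (65.6%) and the 2 profiles correlated with a Spearman rho of 0.946 across bins, so an even gain of X copies stays open. A larger share of inactive X chromatin, which carries H3K27me3, may also account for the difference, but its tests did not decide: peak and gene number correlated across bins (rho 0.469, above the 95% range of the 167 circular shifts of the bins, -0.179 to 0.234; one-sided permutation p = 0.00595, the smallest they can give), as the explanation predicts, but so they did in replicate 2 (0.480) and on autosomes (0.155 to 0.728), and 6 genes that escape inactivation were not less covered (mean 1667 against 827 bp, one-sided permutation p = 0.869). Whether the marking reaches promoters of active genes stays open: in the highest CpG decile replicate 1 marked 24% of 25 X promoters against 9.11% on autosomes (Fisher's exact p = 0.0234), but that was the rate over all of X (23.1%; against the other X promoters, exact p = 1), and no expression was measured here. Replicate 2 and the replicated list each marked 0 of these 25 X promoters. The sex makeup of each pool is not given in the sources used here, so it stays open.

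Midbrain regulators averaged 9369 covered bp around the TSS and hindbrain and spinal regulators 11991, a difference of -2623 bp that narrowly missed the threshold (permutation test, adjusted p = 0.0558). Promoter CpG content was similar in these 2 lists, but whether it is a source of the difference was not settled. Median CpG content, observed over expected, was 0.649 for midbrain and 0.643 for hindbrain and spinal promoters. Subtracting the mean of genes in the same CpG decile took similar amounts from both lists (means 8694 and 11380 bp after it). These amounts were far smaller than the difference, so the subtraction could not have ended it, whatever the cause. A difference of -2686 bp was left (permutation test, p = 0.0237, adjusted p = 0.0474). The choice of TSS stays open for the promoter counts, as any annotated start left a gap of -3.33 percentage points. A lower level of the mark in midbrain cells that use these regulators is a hypothesis that these data do not test, since no other tissue was analysed here.

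The most significant peaks in both replicates and in the pooled list lay on chromosome 17 (39843035 to 39846791 and 39847867 to 39848913 in the pooled list), over the ribosomal RNA gene CT010467.1 and the noncoding RNAs Gm26917 and Gm42418. Their −log10 p was 73.9 and 69.8 in the pooled list, with folds of 2.24 and 2.21. The highest fold of these peaks in any of the 3 called lists was 2.54, below the lowest decile of the 100 most significant peaks in each (7.62 in replicate 1, 6.55 in replicate 2 and 6.70 pooled). The peak ranked next in replicate 1, over 1810010K12Rik on chromosome 2 (19449303 to 19453450), had a fold of 10.16, while the one ranked next in replicate 2 and in the pooled list, over Cdk8 on chromosome 5 (146260999 to 146261489 in the pooled list), had folds of 3.47 and 3.37, also below the lowest decile (both chosen after their values were seen). Ribosomal DNA copies collapsed onto a single reference copy are a candidate explanation that these values do not test, since the low fold is what prompted it, and no biological explanation was tested.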
